A study of Saccharomyces cerevisiae with 26 samples.

How the data were processed

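RNA and histone marks were measured in budding yeast of the CEN.PK strain grown in continuous culture, where oxygen use cycles between an oxidative phase (OX), a reductive building phase (RB) and a reductive charging phase (RC). The labels place time points 1 and 2 in early and late OX, 3 and 4 in early and late RB, and 5 in RC. RNA came from wild type and from the TAF14[W81A] mutant at 5 time points, with replicates A and B, which makes 20 RNA libraries in 10 groups of 2. The other 6 of the 26 samples are ChIP libraries at time points 3 and 4, with no replicate per mark and time point. Whether A and B came from separate cultures is not stated, so every p-value measures only the spread between these samples.

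The deposited RNA table holds 6008 genes, each with 1 log2 level per genotype and time point, per the file headers. It also holds the authors' log2 fold change of mutant over wild type and their adjusted p-value at each time point. The submitters' processing notes name BWA, DESeq2, MACS2 and deepTools and the genome build sacCer3, without versions or roles. The deposited ChIP table holds a signal per gene and position bin for H3K9ac (acetylated lysine 9 of histone H3), with 1 value per time point. Its scale is not stated, nor whether it was divided by H3, nor how genes were binned.

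The 2 libraries behind each deposited level were recovered from its decimals. Multiplied by the length of the gene, the linear level is a sum of whole reads of 2 libraries, each times its own step, within 1.15 times the rounding of the last decimal. The steps were found per group from genes with a RefSeq length (5747 of 6008). The 10 levels were whole reads at the RefSeq length for 5438 genes and at a searched length, always a multiple of 3, for 552, while 18 had no such length. With lengths shuffled between genes, 0.957% of genes gave whole reads. For 1000 genes of known length searched as a control, a length was found for 962, and it was the RefSeq length for all 962. Reads had a single solution in all 10 groups for 5434 genes and in at least 1 group for 5974. Where a group had several solutions, only its mean, known from the deposited level, entered the fit. That mean counted as 2 libraries, and the spread of the gene came from its other groups. The recovery gives no letter, so the libraries are called 1 and 2, and library 1 of a group has no tie to library 1 of another. The lowest recovered value of a gene in a library was 1 read.

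Recovered reads were put on the authors' deposited scaling (reads times the step of the library, without division by length), and log2(scaled reads + 1) was fitted with limma 3.58.1 (trend) in R 4.3.3. Each of the 20 libraries entered 1 fit of 10 group means, with 10 residual and 6.02 prior degrees of freedom. Genes with several solutions in a group had fewer residual degrees of freedom. The pseudocount was 1 and no filter on low values was used, so 5974 genes were tested. Contrasts were F tests over the 5 time points of each genotype, wild-type RB against OX (mean of 3 and 4 minus mean of 1 and 2), RC against OX, RC against RB and time point 4 against 3. Mutant and wild type were compared at each time point and as the mean of the 5 differences, with an F test of the genotype by time interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, two-sided. Log2 changes are given with the SE of the fit. The planned count model in edgeR was not run on the recovered reads.

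Choices made before the data were examined were the contrasts, the tests, 32 gene lists and the rule for named genes. For each contrast, the rule took genes with a standard name, a call, a mean of at least 50 scaled reads and libraries of the compared groups that did not overlap. Of these it named the 8 highest and the 8 lowest log2 changes. A gene with several solutions in a compared group could not be checked for overlap and was not taken, among them NSR1, POX1, CAT2 and ADY2 in RB against OX, CIT2 and GLN1 in time point 4 against 3 and MET14 at time point 4. It added the 3 members of each described list with the largest change among those past the threshold, and 25 genes fixed by name (among them TAF14, GCN5, RPD3, HDA1, ACS1, ACS2, POX1, FOX2, HSP12, SSA3, NSR1, COX4 and ILV5). For the F tests it took the 10 smallest p, and for H3K9ac the 5 highest and 5 lowest changes.

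The lists were cytosolic ribosomal proteins, ribosome biogenesis and RNA polymerase I, mitochondrial ribosomal proteins, respiratory chain and ATP synthase, TCA cycle, fatty acid beta-oxidation, peroxins, fatty acid synthesis, ergosterol synthesis, heat shock proteins and chaperones, oxidative and general stress, trehalose and glycogen, autophagy, proteasome, glycolysis and fermentation, gluconeogenesis with acetate and lactate use, acetyl-CoA supply, amino acid synthesis, sulfur assimilation and methionine, purine synthesis, DNA replication, histones, G2 and mitosis, daughter cell separation, TAF14-containing complexes, histone acylation enzymes, mating type genes, meiosis and sporulation, iron regulon and phosphate regulon. Mitochondrially encoded genes (0 of 8 in the table) and stable non-coding RNAs (0 of 14) could not be tested, which left 30 lists. Camera tested each list against all other genes with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a contrast, and again with the correlation estimated from the residuals. With the preset value 154 of 300 list tests passed, and with the estimated one 4, all in wild type: mitochondrial ribosomal proteins in RB against OX (adjusted p = 0.0328) and in RC against RB (0.000458), ergosterol synthesis (0.00721) and G2 and mitosis (0.038) in RC against RB. Without time point 1 the first of these no longer passed (adjusted p = 0.115). Fry, run on genes with a single solution, passed 193 of its 270 tests; its PValue tests whether the genes of a set move, on balance, in 1 direction, its PValue.Mixed whether they change in either direction, and neither compares the set with other genes. Counts of called list members are over all genes tested, and counts adjusted over the list alone are given where they differ by more than a few genes. Median, mean and test differed in sign in 27 list tests, of which 0 had passed, such as the phosphate regulon in RB against OX (4 higher and 4 lower of 10, median 0.05, mean -0.26).

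In the ChIP table, 281351 of 1048575 lines repeated earlier lines and were left out, and 40 lines had no readable value. Of 70 bins named, the first 57 were complete at both time points for 6008 genes. Among bins 1 to 20 the median signal was highest at bin 11 (0.958) at time point 3 and at bin 12 (0.862) at time point 4. Over all 57 bins it was highest at bin 57 (0.986 and 0.969). Bin 11 was taken as the 5' end of the gene, which the file does not state. The value of a gene was the mean signal over bins 11 to 20, as log2 with a pseudocount of 5% of the mean signal, and changes from 3 to 4 were centred on the median gene (-0.0968 before centring). Without replicates, no test was run. List medians were ranked among 10000 random lists of like size and expression, and genes are not independent replicates. This window, chosen after seeing the data, replaced a planned window in base pairs. H3K9cr (crotonylated lysine 9) and H3 were not analysed here.

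The recovery and the fit were tested on simulated data of 5434 genes and 20 libraries with a dispersion of 0.003. Of 54288 values with a single solution (99.9%), 0 differed from the simulated reads. Of 50 genes each changed by log2 0.3, 0.6, 1 and 2, limma called 22%, 96%, 100% and 100%, with 14 false calls among 5234 unchanged genes. With no gene changed, 6 of 5434 genes and 0 of 27 lists were called. The simulated genes varied independently, with the same dispersion in every group. Real libraries of time point 1 had a larger spread, and genes of a list can vary together. The simulated false calls therefore do not carry over to time point 1 or to the list tests.

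Alternatives tried were upper-quartile scaling (75th percentile), a minimum mean of 10 scaled reads, pseudocounts of 0.1 and 10, each library left out in turn, the 4 libraries of a time point alone, and other list tests. Chosen after seeing the data were the authors' deposited table in place of the fit, genes with a single solution in all groups, leaving out time point 1 (gene and list tests), upper-quartile scaling in the list tests, and other ChIP windows. Under upper-quartile scaling the median of all genes moved by over 0.1 (log2) from 0 in RC against RB, to 0.104, and in no other contrast. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 did the remaining steps.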

Results

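RNA was sequenced from wild-type yeast and from a mutant of TAF14, a shared subunit of TFIID, TFIIF, SWI/SNF, INO80 and NuA3 whose YEATS domain binds acylated histone lysines. The W81A change lies in that domain. Each genotype was sampled at 5 time points of the metabolic cycle, and each of the 10 groups held 2 libraries. Recovered reads were summed over the 5434 genes with a single solution in all 10 groups, so reads of the other genes are not in these sums. The 2 wild-type libraries of time points 1 to 5 held 2790000 and 2810000, 2630000 and 2650000, 2730000 and 3030000, 2830000 and 3190000, and 2020000 and 2770000 such reads. The mutant libraries held 2250000 and 3200000, 3310000 and 3360000, 2990000 and 3610000, 2490000 and 2480000, and 2380000 and 3750000. H3K9ac signal was used at time points 3 and 4, with 1 ChIP library each and unknown depth. All log2 changes are limma estimates ± SE with n = 2 libraries per group, and positions are on sacCer3. A group whose reads had several solutions entered as its mean only, so the SE of that gene rests on its other groups. Genes were named by the rule in the processing section, which passes over genes whose reads had several solutions in a compared group, so genes not named can have larger changes.

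The 2 libraries of a group correlated across genes at a Pearson r of 0.986 in wild type at time point 1 and of 0.991 to 0.993 in the other groups. The median SD between them was 0.122 (log2) in wild type and 0.0922 in the mutant at time point 1, and 0.0542 to 0.0726 in the other groups. Time point 1 therefore stands apart in spread, and counts without it are given in the closing section. The first principal component took 70.3% of the variance and followed the time points. On it the wild-type libraries of time points 3 and 4 lay at 42.6 to 57.2 and the mutant libraries at 21.6 to 33.1.

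**Figure D1:**
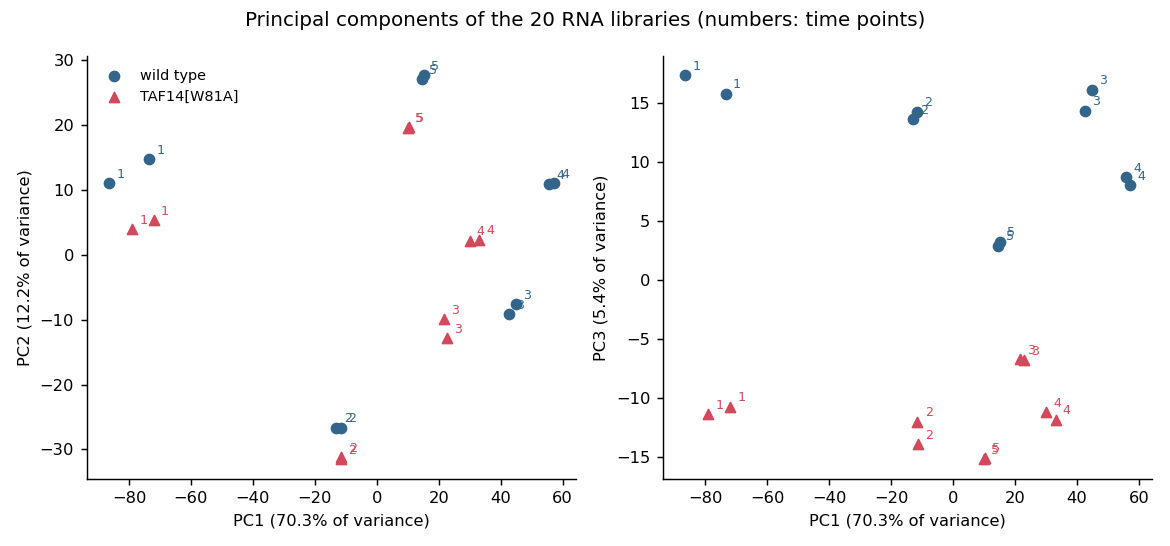
Principal components of the 20 RNA libraries, each point a library, coloured by genotype and numbered by time point, with the percent of variance on each axis. Mutant libraries of time points 3 and 4 lie between 21.6 and 33.1 on the first component, where wild type lies between 42.6 and 57.2, and the third component sets every wild-type library (2.92 to 17.4) apart from every mutant library (-15.2 to -6.67).

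The first question was which transcripts cycle in wild type. Of 5974 genes tested, 5597 changed over the 5 time points. Among the genes with the smallest F-test p-values, MRT4, UTP22, SDA1, RRP5, RPL12A, GPP1, RMT2 and TRM2 had their highest mean at time point 1 and PHM7 at time point 4. MRT4, UTP22, SDA1 and RRP5 act in ribosome assembly and RPL12A is a ribosomal protein. Group means of MRT4 spanned 6.95 (log2), those of UTP22 4.16, those of SDA1 6.19, those of RRP5 5.15 and those of RPL12A 4.09. They spanned 6.60 for the glycerol-3-phosphatase gene GPP1, 5.51 for the arginine methyltransferase gene RMT2, 4.51 for the tRNA methyltransferase gene TRM2 and 6.95 for the membrane protein gene PHM7. The adjusted p was 2.51e-16 for MRT4, UTP22, SDA1, GPP1, RMT2 and PHM7, 2.81e-16 for TRM2, and 3.48e-16 for RPL12A and RRP5. In the mutant, 5471 genes changed over the cycle. Among its smallest p-values were those of PDE2, UTP22 and AAH1, each with an adjusted p of 4.88e-15, and those of HMG1, AIM36, MAL32, PHM7, PRS3 and MRT4.

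Between the RB and OX phases of wild type, genes that build ribosomes fell while genes of lipid, acetate and storage-carbohydrate use rose. The nucleolar protein gene NSR1 (YGR159C, chromosome VII, 806412 to 807656) fell by 6.01 on the log2 scale (SE 0.15, n = 4 libraries per phase, limma adjusted p = 2.7e-15). Its reads had several solutions in a compared group, which entered only as its mean, so its SE rests on its other groups. PWP2 (YCR057C, chromosome III, 220457 to 223228) changed by -5.36 ± 0.10, SSF1 by -5.33 ± 0.11, UTP13 by -5.33 ± 0.13 and the RNA polymerase I subunit gene RPA49 by -5.27 ± 0.12. DRS1 (-4.91 ± 0.12), IMP3 (-4.87 ± 0.17), the tRNA methyltransferase gene TRM11 (-4.96 ± 0.16) and SRO9 (-4.90 ± 0.13) fell as well. Of 129 genes of ribosome biogenesis and RNA polymerase I, 128 fell (median -3.77), and all 127 cytosolic ribosomal protein genes tested fell (median -2.60), RPS9A by -4.12 ± 0.10 and RPL22B by -4.04 ± 0.08. Camera gave these lists adjusted p-values of 2.57e-29 and 5.79e-26 with the preset correlation, and adjusted p = 0.208 for both with an estimated correlation. Without time point 1 the median of the biogenesis genes was -2.34 (126 of 129 fell), and NSR1 changed by -3.30, DRS1 by -3.25 and TRM11 by -2.88.

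The genes of beta-oxidation and acyl transport rose in 18 of 19 cases (median 4.02). POX1, the acyl-CoA oxidase gene (YGL205W, chromosome VII, 108158 to 110404), rose by 6.50 ± 0.29, the carnitine acetyltransferase gene CAT2 by 6.24 ± 0.25, the peroxisomal catalase gene CTA1 by 5.72 ± 0.23, FOX2 by 5.51 ± 0.23, and the peroxisomal transporter genes PXA1 and PXA2 by 5.37 ± 0.21 and 5.27 ± 0.26. All 12 genes of gluconeogenesis, glyoxylate and acetate or lactate use rose (median 3.13), led by the acetate transporter gene ADY2 (7.07 ± 0.24) and the acetyl-CoA synthetase gene ACS1 (6.32 ± 0.23). All 18 trehalose and glycogen genes rose (median 3.19; TSL1 4.95 ± 0.12, PGM2 4.34 ± 0.11), as did 12 of 13 acetyl-CoA supply genes (median 1.37; ALD4 3.34 ± 0.09). Camera gave beta-oxidation 6.76e-06, gluconeogenesis 0.000274, trehalose and glycogen 2.97e-07 and acetyl-CoA supply 0.000917. With an estimated correlation the adjusted p was 0.208, 0.211, 0.208 and 0.208. Outside the lists, SPG1 (6.04 ± 0.25) and PHM7 (6.0 ± 0.09), the transcription factor gene USV1 (4.89 ± 0.16), the transketolase gene TKL2 (4.98 ± 0.15), FMP45 (4.88 ± 0.15) and RTC3 (4.77 ± 0.11) rose. Leaving out time point 1, the median of trehalose and glycogen genes was 1.93 (18 of 18 rose), and the change was 2.97 for TSL1, 2.60 for PGM2, 3.09 for USV1 and 5.18 for ALD4.

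Stress and degradation genes rose with them: 23 of 25 heat shock and chaperone genes (median 1.49; HSP42 3.79 ± 0.17, HSP12 2.86 ± 0.10), 24 of 26 oxidative and general stress genes (2.14; XBP1 4.07 ± 0.19), 29 of 33 autophagy genes (1.10; ATG39 2.87 ± 0.16), 22 of 26 peroxins (0.90; PEX18 2.74 ± 0.15) and 27 of 33 proteasome genes (0.22; RPN4 1.73 ± 0.05). Camera gave them 6.4e-05, 2.48e-06, 2.29e-06, 0.000477 and 0.00164, and with an estimated correlation the adjusted p was 0.22, 0.208, 0.208, 0.208 and 0.22. Of the mitochondrial lists, 71 of 72 ribosomal protein genes rose (median 0.99; MRPL23 1.72 ± 0.06; camera 9.39e-14, and adjusted p = 0.0328 with an estimated correlation). All 15 TCA cycle genes rose (1.41; CIT1 2.32 ± 0.22), as did 29 of 32 respiratory chain genes (0.61; NDI1 1.49 ± 0.07). Their adjusted p of 0.000238 and 3.94e-05 became adjusted p = 0.208 and 0.251 with an estimated correlation. These mitochondrial changes rested on time point 1. Without it the ribosomal protein genes had a median of 0.30 (47 higher and 3 lower of 72; camera 0.000121, and adjusted p = 0.115 with an estimated correlation), the TCA cycle 0.12 (6 and 2 of 11, camera 0.363) and the respiratory chain 0.05 (9 and 6 of 25, camera 0.828). Proteasome genes no longer passed either (0.08, 13 and 2 of 33, camera 0.21), and the median of heat shock genes was 0.77 (19 and 2 of 22). COX4, a cytochrome c oxidase subunit gene, rose by 0.47 ± 0.04, but without time point 1 its change was -0.0898 (adjusted p = 0.095). Leaving that time point out also gave 0.00 for NDI1 (adjusted p = 0.93), 2.45 for HSP42, 2.48 for XBP1, 1.02 for RPN4 and 1.02 for MRPL23.

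Biosynthetic genes fell alongside the ribosome genes: 50 of 55 amino acid genes (median -1.51; LEU9 -3.93 ± 0.15), 20 of 21 sulfur and methionine genes (-2.27; MUP1 -4.49 ± 0.11, SAM1 -3.88 ± 0.07) and 14 of 15 purine genes (-1.95; IMD4 -4.42 ± 0.11). Camera gave 1.57e-10, 2.35e-06 and 7.58e-05, and with an estimated correlation the adjusted p was 0.208, 0.208 and 0.22. Of the cell division lists, all 10 histone genes rose (0.98; HHO1 1.29 ± 0.08) and 11 of 16 G2 and mitosis genes rose (0.40; SWI5 1.69 ± 0.07). All 10 daughter separation genes fell (-1.74; DSE4 -2.54 ± 0.07), as did 39 of 51 replication genes (-0.56; MCM3 -1.71 ± 0.05). Their adjusted p was 0.000523, 0.0269, 0.000684 and 0.000265, and adjusted p = 0.208 for all 4 with an estimated correlation. TAF14 itself fell by 0.66 (SE 0.04, adjusted p = 2.4e-10), and 42 of 60 genes of the complexes that hold it fell (median -0.39, camera 0.00185, adjusted p = 0.208 with an estimated correlation). Glycolysis (11 rose and 3 fell of 18, camera 0.0617), ergosterol (6 and 13 of 24, 0.105), fatty acid synthesis (9 and 3 of 13, 0.183), histone acylation enzymes (10 and 20 of 35, 0.256) and the iron regulon (7 and 3 of 12, 0.267) did not pass as lists. Limma called 2583 genes higher and 2490 lower, 50.9% of the calls higher, and 51.3% with upper-quartile scaling. The medians without time point 1 were 0.60 for histones, -1.03 for daughter separation and -0.18 for the TAF14 complexes, and MUP1 changed by -2.57, IMD4 by -2.81 and DSE4 by -1.22.

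RC against OX asked what stays changed when the culture recharges. Ribosome genes were lower in RC than in the mean of early and late OX: 126 of 127 ribosomal protein genes (median -1.71; RPL9A -2.86 ± 0.06) and 127 of 129 biogenesis genes (-1.63; NSR1 -3.46 ± 0.18) fell. Camera gave 5.31e-26 and 2.34e-21, and adjusted p = 0.238 and 0.225 with an estimated correlation. The fall of biogenesis genes rested on time point 1: against late OX alone 51 of 129 were lower and 13 higher (median -0.19; camera 0.0365, and adjusted p = 0.603 with an estimated correlation), while ribosomal protein genes had a median of -1.37 (126 of 127 lower). Outside them fell GIC2, a Cdc42 effector gene (-4.51 ± 0.14), INA1 (-3.83 ± 0.15), the mating-type endonuclease gene HO (-3.62 ± 0.14), IMD4 of GTP synthesis (-3.55 ± 0.13), BSC1 (-3.45 ± 0.23), the malic enzyme gene MAE1 (-3.24 ± 0.16), PRY2 (-3.19 ± 0.09) and NFG1 (-3.13 ± 0.10). SPG1 (5.95 ± 0.31), FAT3 (5.54 ± 0.26), PXA1 (5.38 ± 0.26), SUE1 (5.00 ± 0.20), the cytosolic catalase gene CTT1 (4.85 ± 0.24), PHM7 (4.80 ± 0.12), HBT1 (4.79 ± 0.15) and GIP2 (4.79 ± 0.21) rose. Higher in RC were 24 of 25 heat shock genes (median 1.84; SSA3 4.64 ± 0.17, HSP12 4.48 ± 0.12), 23 of 26 stress genes (2.20; SIP18 5.03 ± 0.19), 18 of 19 beta-oxidation genes (3.33), all 18 trehalose and glycogen genes (2.26), 31 of 33 autophagy genes (1.08) and all 33 proteasome genes (0.51). Camera gave 5.39e-08, 2.08e-08, 2.2e-07, 4.42e-08, 8.26e-09 and 1.21e-09. With an estimated correlation the adjusted p was 0.225, 0.225, 0.226, 0.238, 0.225 and 0.136. Against late OX alone it was 0.0842, 0.0287, 0.043, 0.163, 0.0287 and 0.0287, so stress, beta-oxidation, autophagy and proteasome genes passed there. In G2 and mitosis 14 of 16 genes rose (1.31; SWI5 2.46 ± 0.09, CLB1 1.98 ± 0.08; camera 7.15e-06, and adjusted p = 0.0629 with an estimated correlation, 0.0287 against late OX alone). By limma, 2127 genes rose and 2456 fell, 46.4% of the calls higher, and 51.3% with upper-quartile scaling. The medians without time point 1 were 0.95 for heat shock, 1.40 for stress and 0.94 for trehalose and glycogen genes, and NSR1 changed by -0.75, IMD4 by -1.94, MAE1 by -1.55 and BSC1 by -0.57 (adjusted p = 0.14).

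From RB to RC the mitochondrial ribosome genes turned down, and the sterol genes and the G2 and mitosis genes turned up. These were the 3 lists that passed with the estimated correlation as well. Of 72 mitochondrial ribosomal protein genes 71 fell (median -1.52; MRPS9 -2.06 ± 0.05, RML2 -1.94 ± 0.05; camera 1.03e-38, 0.000458 estimated). Of 24 ergosterol genes 20 rose (0.59; ERG11 2.47 ± 0.07, ERG25 2.44 ± 0.06, IDI1 2.08 ± 0.05; 1.83e-06, 0.00721 estimated), and of 16 G2 and mitosis genes 12 rose (0.59; KIN3 1.19 ± 0.10; 5.87e-05, 0.038 estimated). Ribosome biogenesis genes rose in 127 of 129 cases (2.14; SSF1 3.72 ± 0.14), ribosomal protein genes in 123 of 127 (0.87; RPS9A 2.19 ± 0.12), daughter separation genes in 10 of 10 (2.42; DSE4 3.24 ± 0.09), and histone genes fell in 10 of 10 (-1.01; HTA2 -2.66 ± 0.08). Camera gave 1.18e-39, 1.19e-23, 2.6e-08 and 1.83e-06. With an estimated correlation the adjusted p was 0.0819, 0.377, 0.0927 and 0.0927. Limma called 1971 genes higher and 1619 lower, 54.9% of the calls higher, and 62.7% with upper-quartile scaling.

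From early to late RB (time point 4 against 3) chaperone genes rose and ribosomal protein genes fell. The HSP70 gene SSA3 (YBL075C, chromosome II, 84499 to 86448) rose by 4.12 ± 0.19, BTN2, which sorts misfolded proteins, by 3.42 ± 0.10, HSP12 by 2.76 ± 0.14, and all 25 heat shock genes rose (median 1.74; camera 5.51e-18, and adjusted p = 0.191 with an estimated correlation). The proton pump gene PMA2 (3.08 ± 0.13), TKL2 (2.97 ± 0.21), HBT1 (2.95 ± 0.18), SPG1 (2.72 ± 0.36), the transcription termination genes NRD1 (2.65 ± 0.09) and HRP1 (2.59 ± 0.07) and SIP18 (2.61 ± 0.22) rose as well. The sodium pump genes ENA1 (-3.19 ± 0.18), ENA2 (-3.29 ± 0.21) and ENA5 (-3.30 ± 0.23), the amino acid permease gene AGP1 (-3.30 ± 0.09), ICY1 (-3.01 ± 0.17), the ammonium permease gene MEP1 (-2.61 ± 0.15), LYS20 (-2.43 ± 0.09) and FCY2 (-2.29 ± 0.12) fell. Stress genes rose in 24 of 26 cases (1.10), proteasome genes in 28 of 33 (0.29), ribosomal protein genes fell in 112 of 127 (-0.59; 115 adjusted over the list alone), replication genes in 38 of 51 (-0.48) and amino acid genes in 35 of 55 (-0.40; GLN1 -2.78 ± 0.13). Camera gave 4.48e-12, 1.26e-08, 1.27e-26, 3.29e-10 and 3.25e-08. With an estimated correlation the adjusted p was 0.191, 0.191, 0.344, 0.191 and 0.344. In beta-oxidation 12 of 19 genes rose (1.29; POT1 2.18 ± 0.22) and 4 fell, with CIT2 at -3.77 ± 0.45 (camera 0.0095, and adjusted p = 0.559 with an estimated correlation). Limma called 1365 genes higher and 1241 lower, 52.4% of the calls higher, and 44.0% with upper-quartile scaling.

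**Figure D2:**
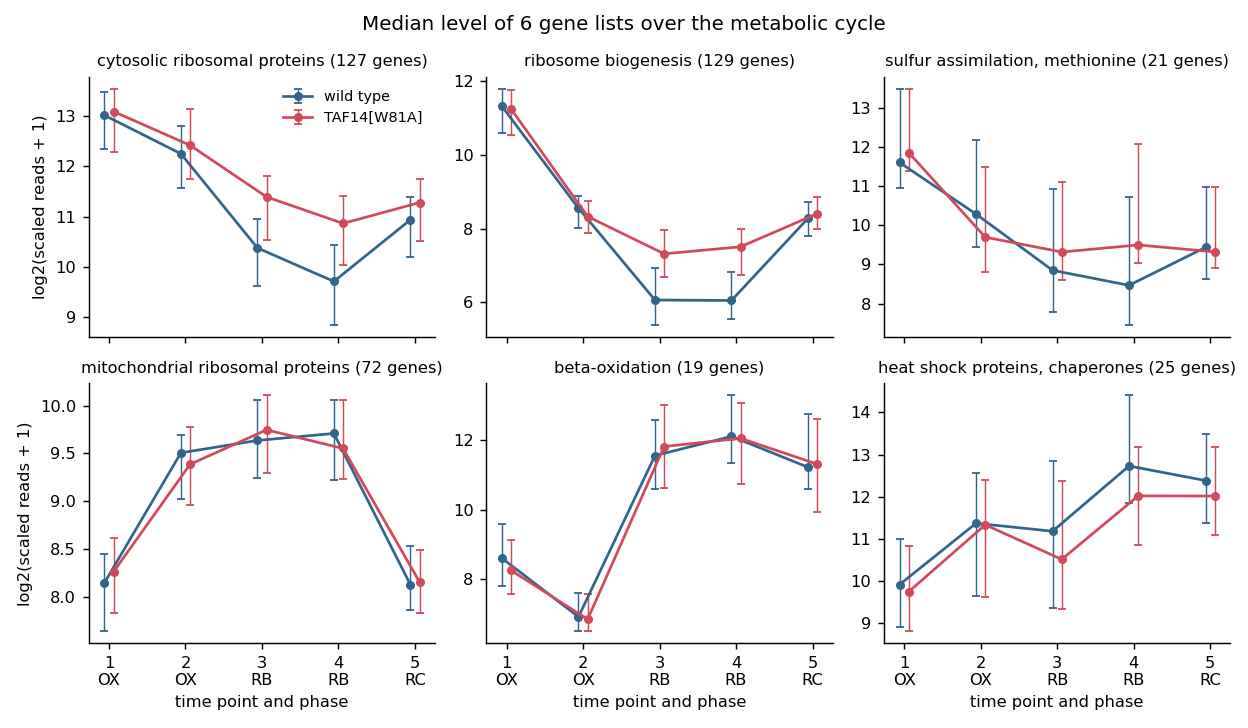
Median log2(scaled reads + 1) of 6 gene lists by time point in wild type (blue) and mutant (red), bars spanning the quartiles of the genes. At time point 4 the median of ribosome biogenesis genes is 6.05 in wild type and 7.51 in the mutant, and that of heat shock genes reaches 12.73 and 12.02.

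The main question was how transcripts differ when TAF14 carries the change. TAF14 RNA (YPL129W, chromosome XVI, 305298 to 306137) was slightly higher in the mutant: by 0.19, 0.38, 0.18, 0.26 and 0.01 at time points 1 to 5, each ± 0.06, with adjusted p = 0.019, 0.00014, 0.025, 0.0028 and 0.95. Its mean difference over the cycle was 0.20 ± 0.03 (adjusted p = 7e-06), and the differences varied between time points (interaction adjusted p = 0.0269). The call at time point 1 ended without library 2 of wild type (0.16, adjusted p = 0.095) and without library 1 of the mutant (0.15, 0.13). At time point 3 it ended without library 1 of wild type (0.21, 0.051), library 2 of wild type (0.15, 0.13) or library 2 of the mutant (0.15, 0.15). At time point 5 the difference lay between -0.05 and 0.06 without single libraries.

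In early OX (time point 1) the mutant had less RNA of glycolysis and of daughter cell separation genes. PDC6, a minor pyruvate decarboxylase gene (YGR087C, chromosome VII, 651290 to 652981), differed by -2.71 ± 0.10 (adjusted p = 2.3e-11), the oligopeptide transporter gene OPT1 by -2.48 ± 0.12, HMS2 by -1.87 ± 0.14, and the ferroxidase gene FET3 and the siderophore transporter gene ARN1 by -1.73 ± 0.10 and -1.62 ± 0.12. HBN1 (-1.70 ± 0.12), AGP3 (-1.67 ± 0.12) and PRY3 (-1.66 ± 0.10) were lower too. Higher were ECM8 (2.22 ± 0.21), the flocculin gene FLO11 (2.03 ± 0.13), the copper transporter gene CTR3 (1.95 ± 0.36), LDS1 (1.89 ± 0.15), GIP2 (1.75 ± 0.24), WSC4 (1.73 ± 0.16), SRL1 (1.68 ± 0.15) and the spore wall gene SPS22 (1.57 ± 0.20). Of 10 daughter separation genes 9 were lower (median -0.95; 10 adjusted over the list alone; DSE2 -1.62 ± 0.09), as were 11 of 18 glycolysis genes (-0.48; ENO1 -1.32 ± 0.11, CDC19 -1.16 ± 0.08), and 19 of 32 respiratory chain genes were higher (0.34; ATP15 0.79 ± 0.11). Camera gave 1.24e-06, 0.00355 and 0.00127, and with an estimated correlation the adjusted p was 0.171, 0.16 and 0.739. Limma called 1424 genes higher and 1516 lower, 48.4% of the calls higher, and 55.5% with upper-quartile scaling. The number rests on the spread shared between groups: the 4 libraries of the time point alone gave 1479 genes, and the authors' deposited table calls 806. POX1 was not called (-0.32 ± 0.41), but it was higher by 0.53 without library 2 of wild type (adjusted p = 0.0192) and differed by -1.16 without library 1 (0.00014), with -0.06 and -0.57 (not called) without library 1 or 2 of the mutant. CTR3 was higher by 1.09 without library 2 of wild type and did not pass with the 4 libraries alone (adjusted p = 0.060). Of the iron regulon 5 of 12 genes were lower (camera 0.0408, and adjusted p = 0.16 with an estimated correlation).

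In late OX (time point 2) the weak-acid exporter gene PDR12 (-2.31 ± 0.10), the sulfonate dioxygenase gene JLP1 (-2.03 ± 0.28), the glycerol transporter gene STL1 (-1.99 ± 0.28), FET3 (-1.96 ± 0.10), HBN1 (-1.86 ± 0.12), HMS2 (-1.65 ± 0.14), ENO1 (-1.60 ± 0.11) and the glycerol kinase gene GUT1 (-1.55 ± 0.16) were lower than in wild type. LDS1 (2.05 ± 0.15), SPS22 (1.77 ± 0.20), the mitotic cyclin gene CLB1 (1.70 ± 0.09), the transcription factor gene SFG1 (1.66 ± 0.10), SRY1 (1.63 ± 0.11), FLO11 (1.33 ± 0.13), MFA1 (1.32 ± 0.24) and SPO74 (1.30 ± 0.19) were higher. All 10 daughter separation genes were lower (median -1.01; DSE2 -1.53 ± 0.09), 15 of 21 sulfur genes were lower (-0.63; SAM1 -1.31 ± 0.10, SUL1 -1.13 ± 0.08) and so were 12 of 18 glycolysis genes (-0.54). Camera gave 2.81e-07, 0.000244 and 0.000244, and with an estimated correlation the adjusted p was 0.281, 0.761 and 0.107. Ribosomal protein genes were higher in 70 of 127 cases and lower in 22 (0.27; 75 and 23 adjusted over the list alone), and biogenesis genes lower in 45 of 129 (-0.21; 39 adjusted over the list alone). Their adjusted p of 0.000244 and 0.00232 became adjusted p = 0.909 for both with an estimated correlation. By limma, 1419 genes were higher and 1427 lower, 49.9% of the calls higher, and 48.8% with upper-quartile scaling.

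In early RB (time point 3) the mutant kept more RNA of the ribosome genes and had less of stress and storage genes. Of 127 ribosomal protein genes 124 were higher (median 0.94; RPS10A 1.34 ± 0.09), and of 129 biogenesis genes 120 were higher (1.25). CGR1 (2.56 ± 0.27), SYO1 (2.55 ± 0.15), MRT4 (2.48 ± 0.10), RPA49 (2.43 ± 0.16) and SSF1 (2.37 ± 0.16), all of ribosome assembly or RNA polymerase I, were higher, as were SFG1 (2.63 ± 0.10), the cell wall transglycosylase gene UTR2 (2.57 ± 0.10) and FLO11 (2.16 ± 0.13). Camera gave the lists 3.08e-39 and 4.6e-36, and with an estimated correlation the adjusted p was 0.332 and 0.211. TKL2 of the pentose phosphate pathway (YBR117C, chromosome II, 474392 to 476437) was lower by 4.07 (SE 0.21, adjusted p = 1.2e-09), with NQM1 (-2.43 ± 0.23) and GND2 (-2.35 ± 0.14) of the same pathway, STL1 (-3.82 ± 0.28), FMP45 (-3.29 ± 0.21), YRO2 (-2.77 ± 0.12), RTC3 (-2.63 ± 0.16) and SIP18 (-2.25 ± 0.22). Stress genes were lower in 16 of 26 cases (-0.52), trehalose and glycogen genes in 12 of 18 (-0.72; GSY2 -1.44 ± 0.18, TPS1 -1.33 ± 0.19) and heat shock genes in 11 of 25 (-0.30; 14 adjusted over the list alone; HSP12 -2.41 ± 0.14). Camera gave 4.79e-05, 4.79e-05 and 0.00915, and with an estimated correlation the adjusted p was 0.422, 0.504 and 0.561. Iron genes were lower in 7 of 12 cases (-0.49; FIT1 -1.76 ± 0.24; camera 0.00697, and adjusted p = 0.211 with an estimated correlation). Limma called 1542 genes higher and 1073 lower, 59.0% of the calls higher, and 65.5% with upper-quartile scaling.

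In late RB (time point 4) ribosomal protein genes were higher in 125 of 127 cases (median 1.04; RPS26B 1.62 ± 0.11) and biogenesis genes in 119 of 129 (1.28; RPA49 2.48 ± 0.16, SSF1 2.33 ± 0.16, IMP3 2.23 ± 0.24), and 19 of 21 sulfur genes were higher (1.34). MUP1, the methionine permease gene (YGR055W, chromosome VII, 599417 to 601141), was higher by 2.84 ± 0.15 (adjusted p = 2.1e-09), with MET14 at 2.45 ± 0.09 and SAM1 at 2.18 ± 0.10. Camera gave 4.64e-39, 6.26e-32 and 3.87e-11, and with an estimated correlation the adjusted p was 0.26, 0.147 and 0.186. UTR2 (2.79 ± 0.10), SFG1 (2.78 ± 0.10), TSR2 (2.22 ± 0.14) and RMT2 (2.21 ± 0.09) were also higher. Heat shock genes were lower in 24 of 25 cases (-1.01; HSP12 -2.63 ± 0.14, SSE2 -1.56 ± 0.23) and stress genes in 21 of 26 (-0.89), with the catalase gene CTT1 at -3.56 ± 0.28, SIP18 at -2.98 ± 0.22 and ALD3 at -2.69 ± 0.18. Camera gave 3.37e-12 and 2.07e-10, and with an estimated correlation the adjusted p was 0.147 for both. TKL2 (-4.83 ± 0.21), FMP45 (-3.56 ± 0.21), HBT1 (-3.54 ± 0.18), PMA2 (-3.31 ± 0.13), YRO2 (-2.91 ± 0.12) and IZH4 (-2.82 ± 0.15) were lower as well.

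Histone genes were lower in 9 of 10 cases at time point 4 (median -0.78; HHT1 -1.09 ± 0.11, HTB1 -0.97 ± 0.06), proteasome genes in 24 of 33 (-0.25; RPN6 -0.69 ± 0.06), glycolysis genes in 10 of 18 (-0.55; ENO1 -1.93 ± 0.11, TDH1 -1.59 ± 0.13) and trehalose and glycogen genes in 12 of 18 (-0.79). Camera gave 4.66e-06, 8.51e-08, 6.72e-05 and 0.000224, and with an estimated correlation the adjusted p was 0.147, 0.147, 0.0932 and 0.545. Beta-oxidation genes did not pass (1 higher and 4 lower of 19, camera 0.134): POX1 differed by -0.60 ± 0.41, FOX2 by -0.34 ± 0.32 and POT1 by -0.05 ± 0.22. Without time point 1, whose libraries had the larger spread, POX1 and FOX2 had the same differences and were called (adjusted p = 8.3e-06 and 0.0089). The deacetylase gene HDA1 was higher by 0.71 ± 0.10, and RPD3 and GCN5 were lower (-0.25 ± 0.06 and -0.31 ± 0.10). The call of GCN5 ended without library 1 or 2 of wild type (-0.33 and -0.28, adjusted p = 0.062 and 0.11) or library 2 of the mutant (-0.23, 0.19), and with upper-quartile scaling (-0.23, 0.077). Limma called 1547 genes higher and 1296 lower, 54.4% of the calls higher, and 65.5% with upper-quartile scaling.

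**Figure D3:**
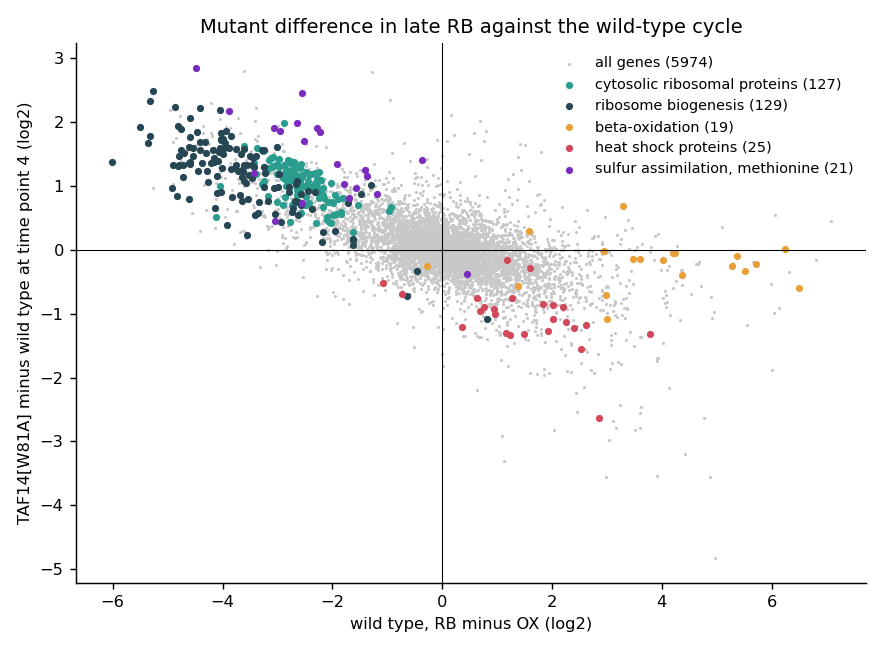
Each of 5974 genes by its wild-type RB minus OX change (horizontal) and its mutant minus wild-type difference at time point 4 (vertical), both log2, with 5 lists coloured. Ribosome biogenesis genes (medians -3.77 and 1.28) lie upper left and heat shock genes (1.49 and -1.01) lower right, while beta-oxidation genes (4.02 and -0.17) lie near the horizontal line.

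In RC (time point 5) CTT1 (-3.47 ± 0.28), FMP45 (-2.56 ± 0.21), TKL2 (-2.35 ± 0.21), STL1 (-2.19 ± 0.28), PMA2 (-2.12 ± 0.13), the malate synthase gene MLS1 (-1.89 ± 0.18), GRE1 (-1.85 ± 0.22) and HBT1 (-1.81 ± 0.18) were lower. UTR2 (2.15 ± 0.10), FLO11 (1.83 ± 0.13), HSP30 (1.66 ± 0.18), SPS22 (1.55 ± 0.20), PRM5 (1.48 ± 0.12), SPO74 (1.32 ± 0.19), the G1 cyclin gene CLN2 (1.31 ± 0.10) and CSS1 (1.31 ± 0.08) were higher. Ribosomal protein genes were higher in 89 of 127 cases (median 0.35; 97 adjusted over the list alone), and amino acid genes were lower in 32 of 55 (-0.27; LYS20 -1.01 ± 0.09, ILV3 -0.83 ± 0.07). Camera gave 6.27e-17 and 2.07e-11, and with an estimated correlation the adjusted p was 0.489 and 0.311. Limma called 902 genes higher and 906 lower, and leaving out any 1 of the 4 libraries gave 1062 to 1144 genes in place of 1808. With upper-quartile scaling 62.8% of the calls were higher, against 49.9%.

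Averaged over the 5 time points, 2269 genes were higher in the mutant and 1907 lower, 54.3% of the calls higher, and 60.8% with upper-quartile scaling. TKL2 (-2.72 ± 0.09), STL1 (-2.29 ± 0.13), FMP45 (-2.23 ± 0.09), RTC3 (-1.81 ± 0.07), PMA2 (-1.80 ± 0.06), HBT1 (-1.64 ± 0.08), GND2 (-1.58 ± 0.06) and the iron-binding wall protein gene FIT3 (-1.36 ± 0.06) were lower. SFG1 (1.89 ± 0.04), UTR2 (1.81 ± 0.05), FLO11 (1.81 ± 0.06), LDS1 (1.80 ± 0.07), SPS22 (1.47 ± 0.09), PRM5 (1.29 ± 0.06), SPO74 (1.22 ± 0.08) and RPC19 (1.14 ± 0.07) were higher. Ribosomal protein genes (116 of 127 higher, median 0.55), biogenesis genes (116 of 129, 0.43) and glycolysis genes (14 of 18 lower, -0.49; ENO1 -1.31 ± 0.05) passed with camera at 5.82e-20, 1.4e-13 and 0.000327. With an estimated correlation the adjusted p was 0.453, 0.431 and 0.114. The genotype by time F test called 2874 genes, with the smallest p-values for SAM1, SRY1 and PDC6 (each adjusted p = 6.38e-09), HRP1, YRO2, MEP3, TPH3, SDA1, FSF1 and FTR1.

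**Figure D4:**
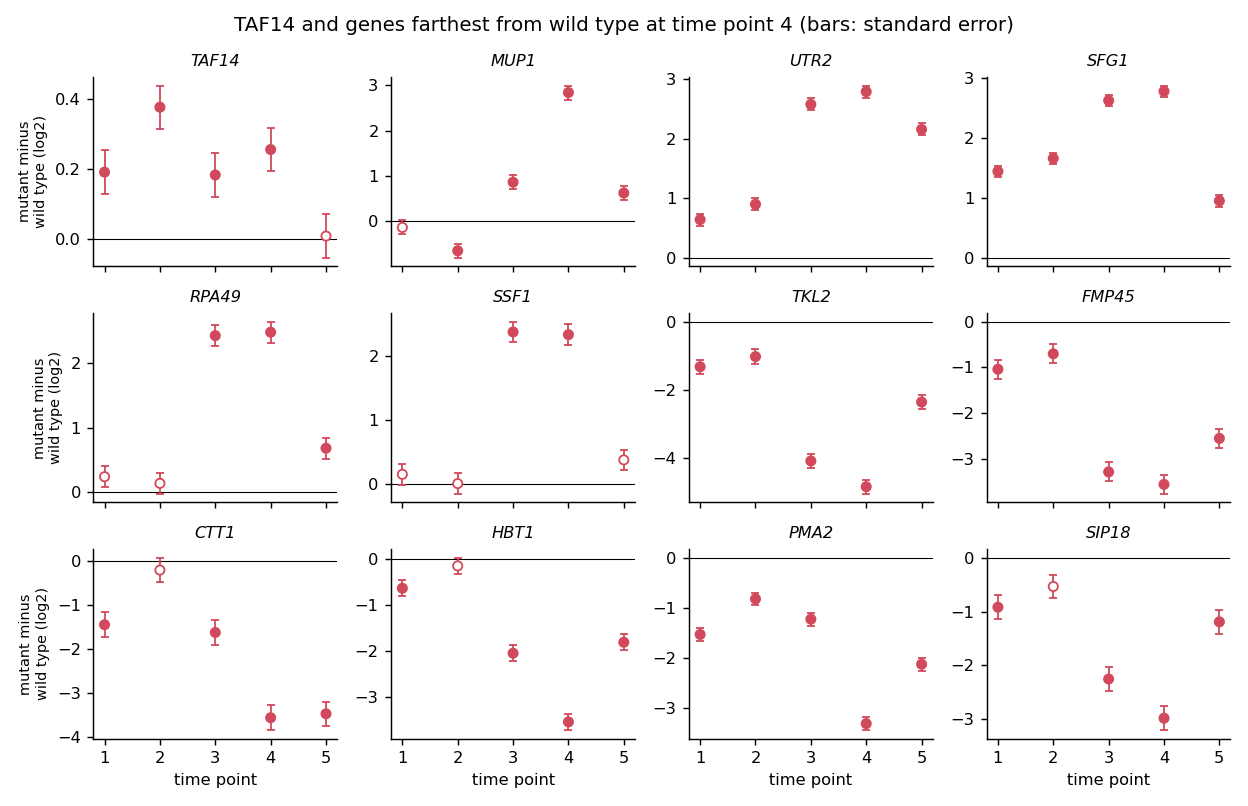
Mutant minus wild-type log2 difference of 12 genes by time point, bars the SE of the fit (n = 2 libraries per group), filled points called and open points not called. SSF1 and MUP1 are highest in RB (2.33 and 2.84 at time point 4), where TKL2 is lowest (-4.83), and UTR2 and SFG1 are higher at each time point.

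The ChIP question was whether H3K9ac over bins 11 to 20, taken as the 5' end of genes, moves with RNA from early to late RB in wild type. Heat shock genes gained most among the 30 lists: their median change was 0.31 (log2, relative to the median gene), above all 10000 random lists, with 24 of 26 genes above the median gene and RNA up in 26 of 26. HSP42 (0.79), SSA3 (0.75) and HSP12 (0.41) gained signal, with RNA changes of 2.44, 4.12 and 2.76. Sulfur genes lost most (-0.28, percentile 0; RNA median -0.33). Mating genes (-0.17, percentile 0.41; RNA median 0.16) and ribosomal protein genes (-0.06, percentile 0.32; RNA median -0.59) also lay under their random ranges. Beta-oxidation genes lay inside the random range (0.12, percentile 96.1; 13 of 19 above the median gene), with POX1 at -0.10, FOX2 at -0.05, CTA1 at 0.13 and POT1 at 0.20 while their RNA changed by 1.55, 2.01, 1.82 and 2.17. The highest single genes were URE2 (0.91), CSM4 (0.85), HSP42, RPS12 (0.78) and GAL2 (0.77), and the lowest GGC1 (-0.89), DAL2 (-0.86), GZF3 (-0.85), GDH1 (-0.84) and FUS3 (-0.79).

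Across 6008 genes, which are not independent replicates, the change of H3K9ac correlated with the RNA change at a Pearson r of 0.154 and a Spearman rho of 0.128. Over bins 11 to 57 the values were 0.0156 and -0.0122. H3K9ac levels were highest in histone genes (medians 1.24 and 1.39 at time points 3 and 4) and lowest in ribosome biogenesis (-0.84 and -0.68) and ribosomal protein genes (-0.67 and -0.71). Genes higher in the mutant had a low wild-type level (1542 genes at time point 3, median -0.22; 1547 genes at time point 4, -0.24), and genes lower in the mutant a higher level (1073 genes, 0.09; 1296 genes, 0.14). The random sets for the higher genes ran from -0.04 to 0.03 and from -0.05 to 0.01, and those for the lower genes from 0.02 to 0.11 and from 0.05 to 0.11. The lower genes thus lay inside their random range at time point 3. Genes not called had medians of 0.034 (3359 genes) and 0.061 (3131 genes). These lay above their random ranges of -0.044 to -0.0022 and -0.0432 to -0.000366, so a raised level was not particular to the lower genes. No test could be run on single libraries, and whether the signal was divided by H3 is unknown.

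**Figure D5:**
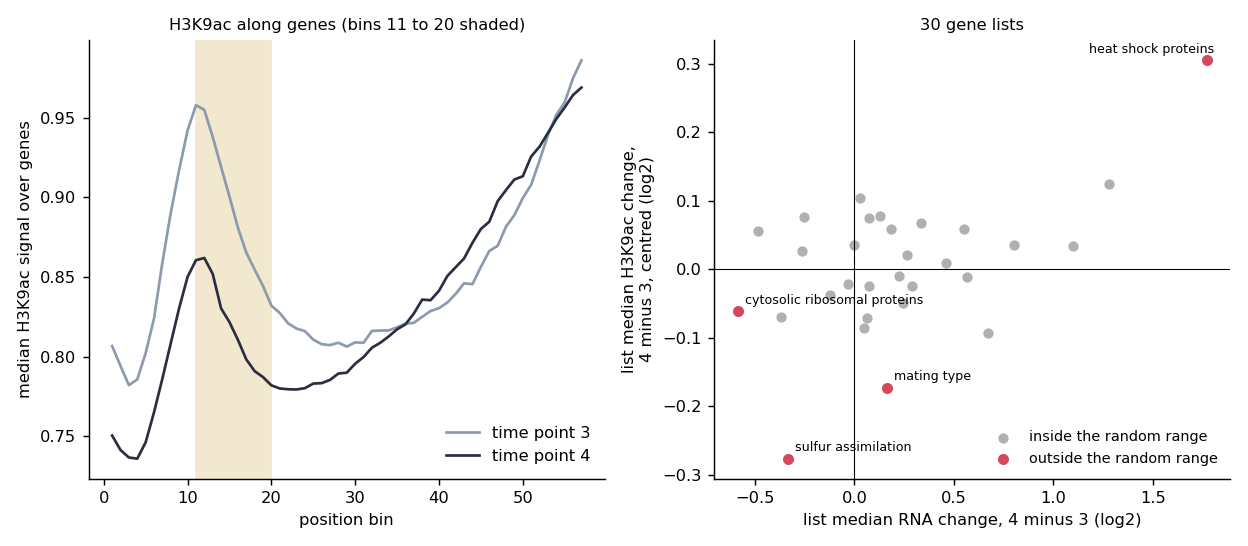
Left, median H3K9ac signal over position bins at time points 3 and 4, with bins 11 to 20 shaded; right, 30 gene lists by median H3K9ac change and median RNA change from time point 3 to 4 (log2), red where the median lies outside the range of random lists. Heat shock genes stand at 0.31 and sulfur genes at -0.28.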

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

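The tests of lower amplitude, of the heat shock and stress genes, of the ribosome genes at time point 3 and of the spread at time point 1 were chosen after the result was seen, as was the difference between the mutant effects at time points 4 and 2.

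The effect of the TAF14 mutation differed between time points in 2874 of 5974 genes (limma interaction F test). Of these, 701 were called higher in the mutant at 1 time point and lower at another. Between time points 2 and 4 the median effect moved by 1.45 (log2) in ribosome biogenesis genes (118 of 129 higher), by 1.87 in sulfur and methionine genes (20 of 21 higher) and by 1.23 in daughter separation genes (10 of 10 higher). It moved by -0.86 in histone genes (9 of 10 lower) and by -1.04 in heat shock genes (24 of 25 lower). Camera gave 9.16e-39, 3.45e-16, 3.3e-08, 1.05e-07 and 2.3e-12, and adjusted p = 0.121 for each with an estimated correlation.

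The first pattern is that ribosome genes were higher and stress genes lower in the mutant in RB. For these libraries, the values argue against a cycle of lower amplitude in every group. Beta-oxidation, TCA cycle and mitochondrial ribosome genes (106 genes, 72 of them mitochondrial ribosomal) kept 93.6% of the wild-type RB against OX change (95% interval 86.0 to 103%). Ribosome genes kept 66.7% (63.6 to 68.4%). Without time point 1, on which the TCA cycle and mitochondrial ribosome changes rested, the 3 lists kept 134% (103 to 169%), beta-oxidation genes alone 97.6% (86.8 to 112%) and ribosome genes 57.9% (53.3 to 60.4%). All intervals in this paragraph resample the genes of a list with the libraries held fixed. They do not measure the spread between libraries or cultures. At time point 4 the ribosome genes stayed 0.88 higher (0.85 to 0.96) than the best matching point of the wild-type cycle. They were also higher than both neighbouring wild-type time points, 3 and 4 (0.65 and 1.12). This argues against a wild-type profile from between those time points. An earlier moment is not excluded. The mutant medians (10.86 for ribosomal proteins, 7.51 for biogenesis) lay between those of wild-type time points 2 (12.25 and 8.55) and 3 (10.38 and 6.07). A share of mutant cells left in an OX-like state is not excluded for the ribosome genes. They showed 10.3% of OX-like signal, and other genes that fall from OX to RB 8.89%. The other genes were not cleared of ribosome assembly genes missing from the lists, such as MRT4 and SYO1. The like shares therefore cannot tell such cells from an effect limited to ribosome assembly genes. Such a share does not account for the heat shock and stress genes, whose -0.96 (-1.22 to -0.86) lies under the -0.18 it allows. OX here is the linear mean of time points 1 and 2, where biogenesis genes had wild-type medians of 11.30 and 8.55. The share was not computed against late OX alone. It would then be larger, and the change it allows lower than -0.18. A shift in timing also stays open for the heat shock and stress genes at time point 4 (-0.27 from the best matching point) and for the ribosome genes at time point 3 (0.53), because 5 time points leave the path between them unknown. Matched on other genes, the mutant at time points 3 and 4 lay 75% of the way from wild-type time point 2 to 3 and 50% from 3 to 4. These matches were loose. The root mean square log2 difference fell from 0.467 at the same time point to 0.403 at time point 3, and from 0.514 to 0.443 at time point 4. Most of the difference thus remained at the best matching points. An effect of the TAF14 mutation itself stays open too.

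The second pattern is that 2940 genes were called at time point 1 here and 806 in the authors' deposited table. A larger spread between its libraries could account for it: the median SD was 1.41 times that of the other time points in the mutant and 1.84 times in wild type, and a fit that shares the spread between groups passes more genes there. The 2 wild-type libraries may have been taken at different points of the cycle, since their difference correlated at an r of 0.647 with the mutant change from time point 5 to 1 and of -0.402 with that from 1 to 2, and the mutant libraries did likewise against the wild-type changes (0.487 and -0.343). No biological explanation was tested.

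The third pattern is that 250 genes were higher and 281 lower in the mutant at all 5 time points. Each of these genes needs a call at time point 1, where a fit that shares the spread passes more genes. That fit called 2940 genes there, its 4 libraries alone gave 1479, and the authors called 806. The counts of 250 and 281 may therefore be too high, and they were not recounted with a separate spread for time point 1. The largest chromosome median was 0.0545 in size, which argues against an extra or missing chromosome in most mutant cells. A gain or loss in few cells, or of part of a chromosome, is not excluded. Of all genes, 8.89% were called at all 5 time points, a share that rests on the same calls at time point 1 and may be too high. Of the 11 genes within 10 kb of TAF14, 0 were called at all 5 time points. This argues against a local effect of the edit that reaches most of these genes at every time point. With only 11 genes, a smaller local effect is not excluded. An effect of the mutation stays open, as do other differences between the strains, which the design cannot separate from it.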

How the results depend on the processing

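The authors' deposited table, genes with a single solution, leaving out time point 1, upper-quartile scaling of list tests and the ChIP windows were alternatives chosen after the data were seen. Of 191 gene counts under alternatives, 185 stayed within 1.5 times. The mutant calls at time point 1 numbered 1479 with its 4 libraries alone and 806 in the authors' deposited table, which use fewer libraries or another test, and at time point 5 they numbered 1062 to 1144 with 1 library left out, where fewer genes were tested and a lone library is assumed to vary like the other groups. For the 1209 results of named genes, of 15204 values under alternatives 14752 kept direction and side of the threshold, 359 lost the call, 90 gained it and 3 reversed: COX4 at -0.0898 in RB against OX and -0.121 in RC against OX without time point 1, and POX1 at time point 1, between -1.16 and 0.532 with 1 library left out. Many of these genes were named for large changes, calls and libraries that did not overlap. Their stability is therefore partly fixed by the naming and says little about other genes. Over all genes, 297 calls made in both settings had opposite directions, all without time point 1: 119 in RB against OX, 176 in RC against OX and 2 in the mean over the cycle. Leaving out that time point, the wild-type cycle gave 5295 genes, RB against OX 4582, RC against OX 4049, the mutant cycle 4898 and the interaction 3210. List tests that passed fell from 154 to 4 of 300 with an estimated correlation. Without time point 1, 0 lists passed with it in RB against OX and 10 in RC against OX: mitochondrial ribosomal proteins, beta-oxidation, peroxins, ergosterol, stress, autophagy, proteasome, replication, G2 and mitosis, and mating. Upper-quartile scaling of the libraries gave 150, with 0 in the opposite direction.

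For H3K9ac, bins 10 to 15, 1 to 20 and 11 to 57 gave 0.187, 0.212 and 0.0156 for the Pearson correlation of the change with RNA and 0.162, 0.186 and -0.0122 for Spearman. Against RNA level, bins 10 to 15 and 11 to 57 gave 0.381 and 0.107 at time point 3, and the 3 windows 0.364, 0.336 and 0.0269 at time point 4. Genes higher minus lower in the mutant gave -0.414, -0.369 and -0.0456 at time point 3 and -0.481, -0.462 and -0.115 at 4. The cause was not tested.

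No paired analysis was possible because the letters A and B of the recovered libraries are unknown, so leaving out series A or B and a replicate block were not run. The planned count model on recovered reads was not run, although reads were recovered for 5974 genes, so how the calls depend on the model is unknown. TMM and median-ratio scaling were not run, nor were H3K9cr and H3 denominators and 500-bp windows. No filter on low values is the setting reported. With 2 libraries per group, simulated changes of log2 0.3 were called in 22% of genes, so small changes can be missed. In that simulation 200 of 5434 genes were changed, while the real comparison at time point 4 called 2843. The Benjamini-Hochberg threshold depends on that number, so the 22% does not carry over to the real comparisons.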

Other observations

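The genes singled out in the next 2 paragraphs were chosen after their values were seen, and no test beyond limma and camera was run on them; both tests of other splits were planned.

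Over the cycle 34 of 60 genes of TFIID, TFIIF, SWI/SNF, INO80, NuA3 and RSC were lower and 14 higher (median -0.13, camera 0.0159, and adjusted p = 0.395 with an estimated correlation), a call that ended without time point 1 (-0.12, camera 0.0534). The INO80 subunit gene IES5 was higher by 0.82 ± 0.05 (n = 10 libraries per genotype, adjusted p = 7.8e-10). Of 35 acylation enzyme genes 7 were higher and 14 lower, which did not pass as a list (camera 0.0754). SGF29 of SAGA differed by -0.62 ± 0.06, EPL1 of NuA4 by -0.50 ± 0.03, the deacetylase gene RPD3 by -0.29 ± 0.03 and the acetyl-CoA synthetase gene ACS2 by -0.26 ± 0.03, each with a call. Fatty acid synthesis genes did not pass (5 higher and 5 lower of 13, camera 0.929). The peroxin gene PEX2 was lower at each time point, by -0.76 ± 0.09 to -1.12 ± 0.09.

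Part of the mating and meiosis genes were higher in the mutant. Of 18 mating genes 11 were higher over the cycle and 2 lower (median 0.30, camera 0.0316, and adjusted p = 0.395 with an estimated correlation). The a-specific genes AGA2 (1.25 ± 0.15), MFA2 (0.97 ± 0.22) and MFA1 (0.73 ± 0.11) were higher. Their levels stayed low in both strains beside the alpha-specific genes: at time point 2, AGA2 had a mean log2 level of 2.95 in wild type and 5.19 in the mutant, and STE3 13.01 and 13.21. Of 24 meiosis genes 7 were higher in RC and 0 lower (median 0.32, camera 0.0148, and adjusted p = 0.215 with an estimated correlation), and the sporulation kinase gene SPS1 was higher over the cycle by 0.89 ± 0.07. The meiosis list did not pass over the cycle without time point 1 (12 higher and 3 lower, camera 0.281). At time point 4 its median deposited level was 4.47 in wild type and 4.32 in the mutant.

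Other splits of the samples were counted over genes with a single solution. For wild-type RB against OX, 1 of 35 splits of the 8 libraries gave as many genes, the real one with 3038, and the highest other gave 3. The 2 libraries of a time point were alike, and other splits put the phase difference into the spread, which keeps their counts low. The low counts are therefore no strong support. For mutant against wild type over the cycle, 1 of 100 splits gave as many, the real one with 3745. The highest other gave 2620. That split swapped the genotypes of all libraries at 4 of the 5 time points, so it shares most of the real comparison with its sign turned. Both kinds of split treat libraries as independent. Whether A and B came from separate cultures is not stated, so a difference between cultures is not excluded.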
